A study of uncultured soil microorganism with 18 samples.

How the data were processed

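Soil DNA of 18 samples of Tibetan grassland, 6 per precipitation treatment, was measured on a 1-colour functional gene array. Per the labels' protocols, DNA was extracted by grinding frozen soil, cleaned on agarose gels, quantified by PicoGreen fluorescence, labelled with the dye Cy5 by random priming and hybridised to a GeoChip. The deposited values are intensities on a linear scale, 1 column per array, and the authors marked the table as not normalized. Each of the 103376 rows, called a probe here, has its own identifier, a gene name (1262 in all), 1 of 12 functional categories, a source organism and its lineage, as deposited. Blank cells show that probes were filtered per array before deposit. The filter, the scanner software and any background correction are not given in the sources used here. The number of listed probes and everything that treats a blank as 0 therefore depend on that filter. A blank was read as not listed on that array, not as absence of the gene from the soil.

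Arrays were assigned to control, dry and wet from the labels, and every column matched 1 sample title. In R 4.3.3, probes listed on at least 4 of the 6 arrays of at least 1 group were taken to log2, quantile-normalized between arrays with blanks as missing, and tested with limma 3.58.1 (group means, moderated variances, all 18 arrays sharing 1 estimate of the spread). P-values were adjusted by Benjamini-Hochberg within each comparison, with 0.05 as the threshold. A gene family was the set of probes with the same gene name as the file writes it. Its value was log2 of its share of the array's total signal, blanks counting as 0, for the 669 families with at least 5 probes listed on any array. In 9 of these families at least 1 array was at 0, and such arrays were left out of the log2 fit of that family. A share moves when any other share moves, so a very bright value elsewhere on an array lowers it. The same threshold applied, with 95% intervals from the limma fit.

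Probes listed per array and the Shannon index of the signal shares were compared by exact two-sided permutation tests over the 924 arrangements of 6 against 6 arrays, whose smallest p is 0.00216, adjusted over the 3 pairs. Composition was compared by PERMANOVA on Bray-Curtis distances of log2(ppm of the array total + 1), exact for pairs and with 100000 permutations for all groups. Distances to group centres came from betadisper in vegan 2.7.1 and were compared by the same permutation test over all arrangements. The centres were not recomputed in each arrangement, so p-values for these distances are approximate. Gene lists were tested with limma's camera at a preset correlation of 0.01 and with a correlation estimated from the residuals. The lists were 25 sets of carbon, nitrogen, phosphorus, sulfur and stress genes fixed before the data were examined, the 12 categories and 4 sets by organism.

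Before the data were examined, the genes to be named were set as the 6 families with the largest increase and the 6 with the largest decrease among those passing, filled to 3 in each direction by smallest p, and 21 families of element cycling and stress. The alternatives planned then were other scalings, filters, offsets, variance models, family values, distances, the fit of only the groups compared, a block for the replicate number, and each array left out in turn. Added after seeing the data were settings without isolated bright values, probes listed on at least 3 arrays of each group, permutation tests of list shares, and alternatives for the distance to group centres. An isolated bright value was more than 4-fold above the median of the same probe on the other arrays, or above 4096 on a probe listed on at most 3 arrays. There were 513 among 1006160 listed values (0.0510%), from 6 on control replicate 2 to 105 on wet replicate 4. The limma steps were tested on simulated data made from the real arrays, with the group means removed, group labels reassigned and known changes added, in 5 sets. At most 12 probes and 2 families in a set were called that had not been changed. Removing the group means set a value alone in its group to the mean of its probe. False calls that rest on such lone values may therefore be undercounted. Figures were drawn with matplotlib 3.10.9.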

Results

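The data were intensities from a GeoChip, a microarray whose probes target genes of known function in soil microorganisms, hybridised with DNA from grassland soil of the Tibetan Plateau. The 18 soil samples, 1 array each, fell into 3 precipitation groups of 6 arrays: control (0% change), dry (-50%) and wet (50% more). The question the labels give is whether altered precipitation changed the functional gene content of the soil community. DNA was labelled, so the signal says nothing of expression, and a signal on probes of RNA viruses is not a measure of viral genomes. The series description places the samples in 3 plots with 6 replicates in each, so each treatment appears to stand for 1 plot. The labels do not say that replicates were independent plots, and every p-value here measures only the spread between samples within a treatment, which may be spatial or technical. Values after ± are SDs over the 6 arrays of a group.

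Of 103376 probes, 83163 had an intensity on at least 1 array and 38970 (37.7%) on all 18. An array listed between 49590 probes (dry replicate 4) and 60925 (wet replicate 4), with a median of 55984.5. Median intensity ran from 752 (control replicate 3) to 1124 (dry replicate 4), between 2.14 and 3.14 times the lowest intensity listed on the same array. Arrays with a higher lowest listed intensity listed fewer probes over the 18 arrays (Pearson's r = -0.729, permutation p = 5.8e-04; Spearman's rho = -0.688, permutation p = 0.00218). Without the 2 arrays farthest from the median lowest intensity, r was -0.628, and within the groups rho was -0.543 in control (exact p = 0.297), -0.943 in dry (exact p = 0.0167) and -0.771 in wet arrays (exact p = 0.103). This was the only such relation computed. Across the 38970 probes listed on all 18 arrays, log2 intensities of array pairs correlated at 0.953 to 0.985 within groups and at 0.953 to 0.988 between groups. Probes are not independent replicates. The number of arrays limits the precision of each group value.

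Probes of bacterial genes carried 93.2% ± 0.259 of the signal of control arrays, probes of fungi 2.90% ± 0.191, of archaea 2.24% ± 0.0406 and of viruses 0.475% ± 0.0185. The gene family with the highest share was MFS_antibiotic, the major facilitator transporters linked to antibiotic efflux, with 10.9% ± 0.392 of the control signal, 10.7% ± 0.395 of the dry and 10.5% ± 0.525 of the wet signal. The Mex efflux pumps followed with 3.58% ± 0.109, 3.59% ± 0.159 and 3.51% ± 0.170 in the same order. The nickel transport gene nikA held 3.11% ± 0.112, 3.04% ± 0.0972 and 3.01% ± 0.153, and amyA, the alpha-amylase that cleaves starch, 3.05% ± 0.0998, 3.00% ± 0.0976 and 2.95% ± 0.0955. The osmotic response regulator ompR held 2.17% ± 0.0805, 2.14% ± 0.0950 and 2.09% ± 0.113. These 5 families were named by their control share after the values were seen, and none passed the test in any comparison. Shares by organism and by family depend on how many probes the array carries for each. Listed probes numbered 74602 for bacteria, 3792 for fungi and 2392 for archaea, and 2734 for amyA. The shares therefore do not give the abundance of organisms or genes in the soil.

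**Figure D1:**
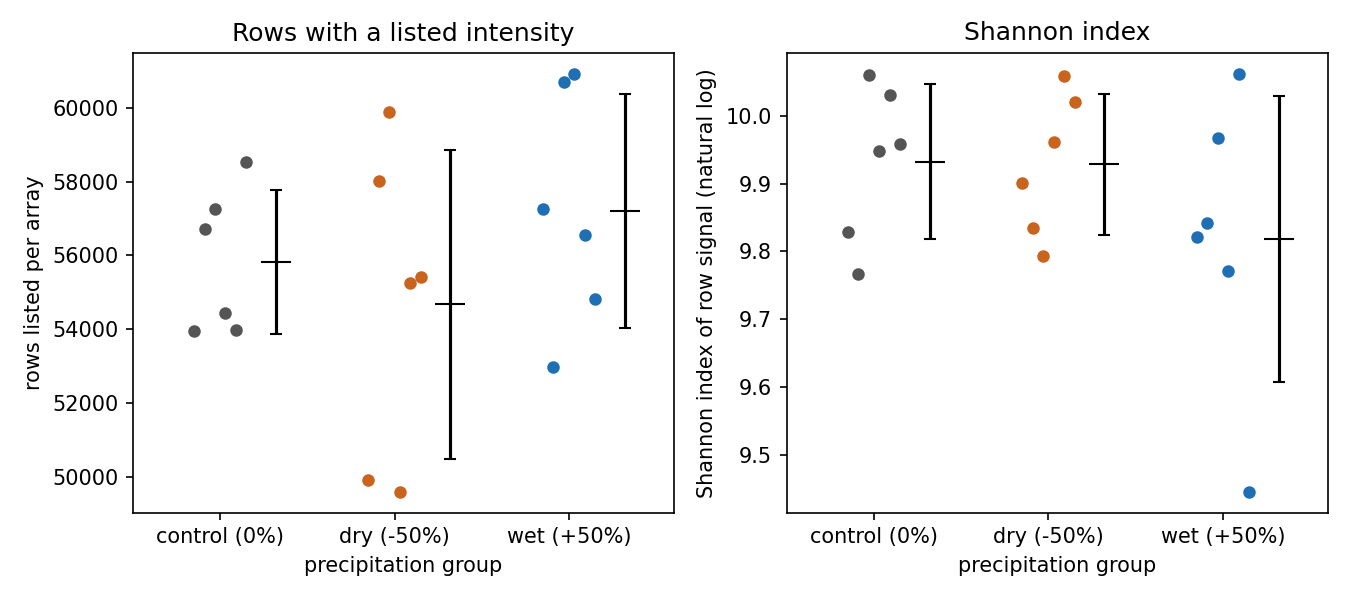
Probes listed per array (left, count) and Shannon index of the probe signal (right, natural log units), with 1 point per array and the group mean with its SD as a bar. The groups overlap in both panels, and wet replicate 6 has the lowest Shannon index at 9.45.

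The first comparison, dry against control, asked whether soil under 50% less precipitation differed in its genes. No gene family passed the test: limma called 0 of 669 families higher and 0 lower, with 7 at an unadjusted p under 0.05 (2 higher, 5 lower) and a smallest adjusted p of 1.000. Among nitrogen cycling genes, nifh, the nitrogenase reductase of nitrogen fixation, held 4360 ± 193 against 4358 ± 146 ppm of the array signal in dry against control arrays (log2 change 0.00022, 95% interval -0.10 to 0.10). The nitrate reductase narg held 7940 ± 248 against 7873 ± 264 ppm (log2 change 0.012, 95% interval -0.068 to 0.092), and the nitrous oxide reductase nosz 3326 ± 161 against 3294 ± 154 ppm (log2 change 0.014, 95% interval -0.079 to 0.11). The ammonia monooxygenase amoa, with 7 listed probes, had the lowest estimate of the 21 families chosen beforehand (log2 change -0.17, 95% interval -0.44 to 0.10), at 102 ± 15.5 against 114 ± 20.4 ppm. The urease gene urec (-0.017, -0.090 to 0.056) and the glutamate dehydrogenase gdh (-0.084, -0.23 to 0.067) had estimates below 0, given here and from here on as the log2 change followed by its 95% interval, and both intervals included 0.

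The carbon families amyA (-0.023, -0.091 to 0.045), chitinase (-0.0052, -0.077 to 0.066), xyla (-0.0077, -0.089 to 0.073) and phenol_oxidase (0.031, -0.084 to 0.15), which act on starch, chitin, hemicellulose sugars and phenolic compounds, stayed within narrow intervals around 0. The methyl-coenzyme M reductase mcra of methanogens was at -0.066 (-0.19 to 0.057), the methane monooxygenase pmoa of methane oxidisers at 0.033 (-0.066 to 0.13), and the carbon-fixing rubisco at -0.020 (-0.11 to 0.075). Nitrite reductases nirk and nirs were at -0.0070 (-0.29 to 0.28) and -0.018 (-0.11 to 0.073), and nrfa, which reduces nitrite to ammonium, at 0.0054 (-0.084 to 0.094). The nirk interval takes its width from the spread shared with the wet arrays. The SD of the nirk share was 57.6 ppm in dry, 54.8 in control and 1065 in wet arrays. The exopolyphosphatase ppx had the highest estimate of the 21 (log2 change 0.076, 95% interval -0.045 to 0.20), and without dry replicate 3 it was 0.00998. Phytase (-0.042, -0.13 to 0.049), the sulfite reductase dsra (-0.0042, -0.10 to 0.092), the osmoprotectant transporter proV (0.026, -0.054 to 0.11) and the chaperone dnaK (-0.019, -0.12 to 0.086) completed the set. In all, 8 of the 21 estimates lay above 0 and 13 below, and none passed when adjusted over the list alone (limma, smallest adjusted p = 0.996).

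Outside those 21, the families with the smallest p in each direction did not pass either (adjusted p = 1.000 for each). Hmd, a methylenetetrahydromethanopterin dehydrogenase of methanogens with 6 listed probes, held 21.2 ± 23.2 against 6.17 ± 0.646 ppm (log2 change 1.28, 95% interval 0.47 to 2.09; 6 of 6 dry arrays above the control mean), and 0.85 without dry replicate 3. The ferric_reductase_transporter family was at 0.36 (0.093 to 0.62), or 0.22 without dry replicate 6, and the plant virus gene replicase_Carmovirus at 0.16 (-0.0066 to 0.33). On the lower side stood bacA, of the file's secondary metabolism category (-0.88, -1.65 to -0.11), the phage gene endolysin_transglycosylase (-0.15, -0.27 to -0.021) and glutamate_synthase_protist (-0.37, -0.68 to -0.052), the last at -0.21 without control replicate 6 and at -0.15 without isolated bright values. The bacA estimate rested on the 5 dry and 4 control arrays above 0, and with the arrays at 0 included bacA held 4.18 ± 2.29 against 6.59 ± 6.51 ppm.

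The 25 gene lists fixed beforehand did not separate dry from control arrays. For carbon, dry against control shares of the array signal were 3.46% ± 0.114 against 3.51% ± 0.0992 for starch degradation, 1.29% ± 0.0328 against 1.36% ± 0.145 for hemicellulose, 0.685% ± 0.0338 against 0.680% ± 0.0192 for cellulose, 1.40% ± 0.0917 against 1.35% ± 0.0420 for chitin, 0.786% ± 0.0225 against 0.810% ± 0.0284 for pectin and 0.883% ± 0.0296 against 0.884% ± 0.0118 for lignin and aromatics. Carbon fixation held 1.35% ± 0.0553 against 1.34% ± 0.0394 and methane genes 0.311% ± 0.0145 against 0.322% ± 0.0122. For nitrogen, fixation held 0.436% ± 0.0193 against 0.436% ± 0.0146, nitrification 0.0341% ± 0.00213 against 0.0353% ± 0.00212, denitrification 1.79% ± 0.0527 against 1.78% ± 0.0577, ammonification and urea 0.917% ± 0.0430 against 0.948% ± 0.0348, reduction of nitrate and nitrite to ammonium or for assimilation 0.337% ± 0.0103 against 0.337% ± 0.0149, and anaerobic ammonium oxidation 0.00388% ± 5.71e-04 against 0.00398% ± 7.59e-04. Phosphorus genes held 1.36% ± 0.101 against 1.31% ± 0.0168 and sulfur genes 2.21% ± 0.0433 against 2.24% ± 0.0240. Among stress genes, shares were 2.29% ± 0.0975 against 2.32% ± 0.0784 for osmotic stress, 0.918% ± 0.0265 against 0.911% ± 0.0144 for heat shock and protein stress, 0.187% ± 0.0104 against 0.190% ± 0.00599 for cold shock and 1.35% ± 0.0331 against 1.37% ± 0.0281 for oxidative stress. Genes of oxygen limitation held 2.43% ± 0.112 against 2.40% ± 0.0437, of nitrogen limitation 0.598% ± 0.0164 against 0.596% ± 0.0173, of phosphate limitation 1.26% ± 0.0674 against 1.25% ± 0.0197, of glucose limitation 0.0603% ± 0.00350 against 0.0602% ± 0.00361, and sigma factors 2.55% ± 0.0724 against 2.56% ± 0.0488. Medians of the probe changes in these lists lay between -0.035 and -0.0032, beside -0.026 over all probes. Over these lists, 53 of 123 family estimates lay above 0 and 70 below, with 0 at an unadjusted p under 0.05. Together with the 12 functional categories of the file and 4 lists by organism, 41 lists were tested with camera, which called 0 (0 at an unadjusted p under 0.05, smallest adjusted p = 0.997, and 0.781 with an estimated correlation). The exact permutation test of each list's share called 0 as well, with 0 at an unadjusted p under 0.05.

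Among single probes, limma called 2 of 56366 higher and 0 lower in dry against control arrays, with 1861 (3.30%) at an unadjusted p under 0.05. Both were named after their values were seen, and both had a value on 1 dry array alone. The nagg probe 169857040, an aromatic acid degradation gene of the mushroom Coprinopsis cinerea, stood at an intensity of 9864 on dry replicate 4 and at 419 to 651 on 7 control and wet arrays (log2 change 4.26 ± 0.17 SE, adjusted p = 1.2e-07). That dry value is 1 of the isolated bright values, and nagg was listed on 1 dry array against 4 control arrays. The Mex efflux probe 170695212 of Burkholderia graminis stood at 1517 on dry replicate 1 and at 310 to 532 on 6 other arrays. Its log2 change was 1.75 ± 0.20 SE (limma, adjusted p = 0.0311). The lowest intensity listed for any probe on dry replicate 1 was 436, above several of those 6 Mex values. Leaving out 1 array moved the count between 0 and 6, with 0 without dry replicate 4, 1 without control replicate 3, dry replicate 1 or any of wet replicates 3 to 6, 4 without control replicate 1 and 6 without dry replicate 2. Limma called 0 among probes that at least 3 arrays of each group listed, a filter that removed both.

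**Figure D2:**
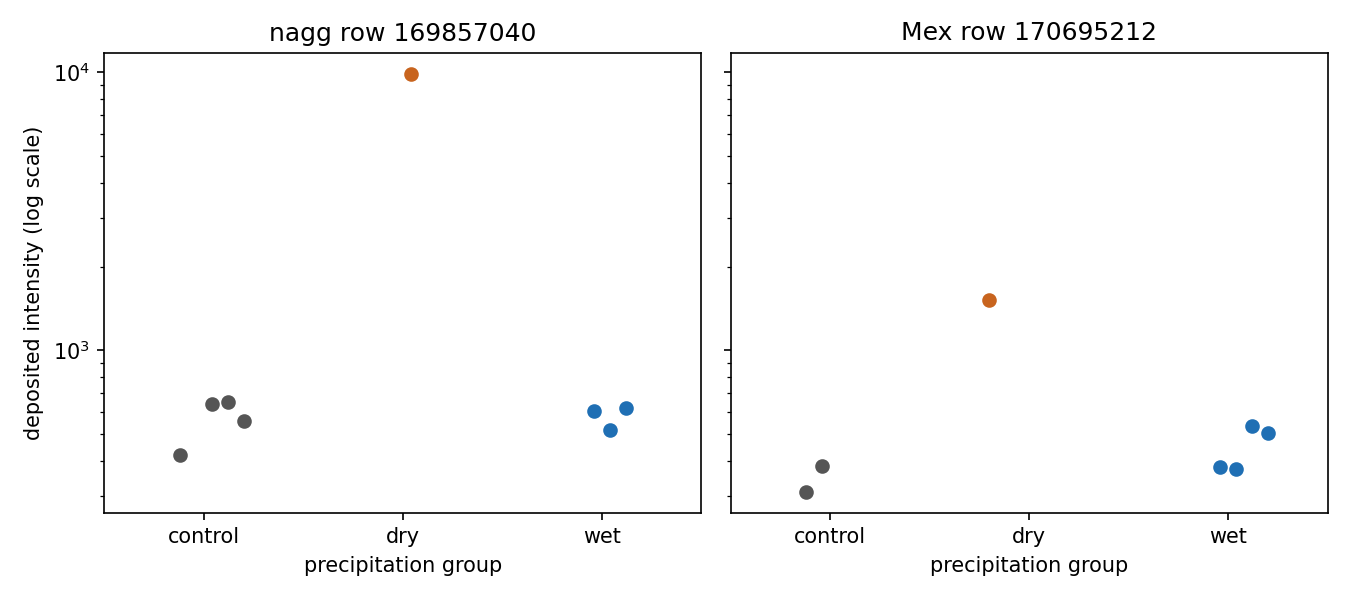
Deposited intensity (log axis) of the nagg probe (left) and the Mex probe (right) on each array that listed it, by precipitation group. Each probe has 1 dry value, 9864 for nagg and 1517 for Mex, above all values of the other groups.

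Dry arrays listed 54675 ± 4192 probes and control arrays 55813 ± 1956 (exact permutation test, two-sided, adjusted p = 0.541, n = 6 each). Their Shannon indices of 9.93 ± 0.104 and 9.93 ± 0.114 did not differ by the same exact test (adjusted p = 0.959).

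The second comparison, wet against control, asked the same of 50% more precipitation. Limma called 0 of 669 families higher and 0 lower, with 15 at an unadjusted p under 0.05 (1 higher, 14 lower) and a smallest adjusted p of 0.949. The nitrite reductase nirk had the highest estimate of the 21 chosen families (log2 change 0.17, 95% interval -0.11 to 0.46), at 2961 ± 1065 against 2520 ± 54.8 ppm, and 0.0038 without wet replicate 4. The lowest was gdh, at 3939 ± 370.0 against 4292 ± 342 ppm (log2 change -0.13, 95% interval -0.28 to 0.025). Nitrogen genes nifh (0.012, -0.085 to 0.11), amoa (0.043, -0.23 to 0.32), narg (-0.014, -0.094 to 0.065), nirs (0.042, -0.048 to 0.13), nosz (-0.028, -0.12 to 0.065), nrfa (-0.021, -0.11 to 0.068) and urec (-0.045, -0.12 to 0.028) all had intervals that included 0. So did amyA, at 29497 ± 955 against 30524 ± 998 ppm (-0.049, -0.12 to 0.018; 6 of 6 wet arrays below the control mean).

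Estimates for xyla (-0.025, -0.11 to 0.056), chitinase (-0.027, -0.10 to 0.044), phenol_oxidase (-0.0060, -0.12 to 0.11), rubisco (-0.027, -0.12 to 0.068), mcra (-0.017, -0.14 to 0.11) and pmoa (-0.029, -0.13 to 0.070) lay just below 0. The same held for phytase (-0.063, -0.15 to 0.028), ppx (-0.044, -0.16 to 0.077), dsra (-0.019, -0.12 to 0.077), proV (-0.0071, -0.087 to 0.073) and dnaK (-0.011, -0.12 to 0.093). Of the 21 families 4 lay above 0 and 17 below, none passing when adjusted over the list alone (limma, smallest adjusted p = 0.894). Over all families 75.3% lay below 0, and 49.5% once 513 isolated bright values were left out. Without those values limma gave 11 families at an unadjusted p under 0.05 (7 higher, 4 lower). On wet replicate 6 a single value of 10252300, on an RdRp_Picornavirales probe of Human rhinovirus 26, made up 8.24% of the signal and so lowered every other share on that array. The highest values of the other arrays lay between 356623 and 798624. All of these, like 87 of the isolated bright values, exceed what a 16-bit scanner can record in a pixel, and how the deposited intensities were scaled is not given in the sources used here.

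The families with the smallest p were P450, cytochromes of the electron transfer category (log2 change -0.17, 95% interval -0.27 to -0.069; 6 of 6 wet arrays below the control mean), the dye-decolourising peroxidase Dyp (log2 change -0.34, 95% interval -0.58 to -0.095; 6 of 6) and the acetylxylan esterase axe (log2 change -0.10, 95% interval -0.17 to -0.027; 6 of 6), all with a limma adjusted p of 0.949. Without isolated bright values axe was at -0.041. Above 0 stood atr1 (0.62, 0.044 to 1.20), the siderophore gene sidC (0.30, -0.015 to 0.62) and the rotavirus coat gene VP7_Gserotype_Rotavirus (0.80, -0.056 to 1.65). The VP7_Gserotype_Rotavirus estimate rested on the 5 wet and 5 control arrays above 0. Without control replicate 5, sidC was at 0.15. Adjusted over the list alone, 1 of the 5 families of the cellulose degradation list passed (axe, placed there although it acts on xylan). So did 1 of the 10 families of the file's electron transfer category (P450), against 0 over all families tested. Both are among the families just named for their smallest p, so these passes are no further evidence. The adjustment was made within each list and not over the 41 lists. The cellulose degradation list held 0.658% ± 0.0211 against 0.680% ± 0.0192 of the signal in wet against control arrays. All 5 of its tested families had estimates below 0, although the median change of the list's probes was 0.0052. The difference in this share did not pass (exact permutation p = 0.0887, adjusted p = 0.867, and unadjusted exact p = 0.526 without isolated bright values).

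Of the 25 fixed lists, 7 had a higher and 18 a lower share in wet than in control arrays. Wet arrays gave 0.440% ± 0.0329 of their signal to nitrogen fixation, 0.0351% ± 0.00320 to nitrification, 1.82% ± 0.107 to denitrification and 0.897% ± 0.0482 to ammonification and urea, beside the control values above. Bacterial probes held 92.0% ± 3.27 and viral probes 1.84% ± 3.36, and wet replicate 6 alone had 85.3% and 8.69%. Starch degradation held 3.46% ± 0.222, chitin degradation 1.32% ± 0.0498, methane genes 0.315% ± 0.0215, osmotic stress 2.24% ± 0.118 and heat shock 0.902% ± 0.0466. The phosphorus genes phytase, ppk and ppx held 1.27% ± 0.0359 against 1.31% ± 0.0168 (exact permutation p = 0.0173, adjusted p = 0.710, and unadjusted exact p = 0.325 without isolated bright values), and the median change of their probes, 0.010, had the other sign. Camera called 0 of the 41 lists, with 1 at an unadjusted p under 0.05, glucose limitation (smallest adjusted p = 0.994, and 0.968 with an estimated correlation). Medians of the probe changes in the lists lay between -0.022 and 0.048, beside 0.015 over all probes. The exact permutation test of the shares also called 0, with 1 at an unadjusted p under 0.05.

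For single probes limma called 0 of 56484, with 1276 (2.26%) at an unadjusted p under 0.05. It called 2 without control replicate 1 or 2, and 1 without control replicate 4 or 6 or wet replicate 5. Wet arrays listed 57205 ± 3167 probes (exact permutation test against control, two-sided, adjusted p = 0.541, n = 6 each). Their Shannon index was 9.82 ± 0.211, against 9.93 ± 0.114 in control arrays (exact adjusted p = 0.468). This difference of -0.114 was -0.0019 without isolated bright values and 0.024 on quantile-normalized intensities.

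**Figure D3:**
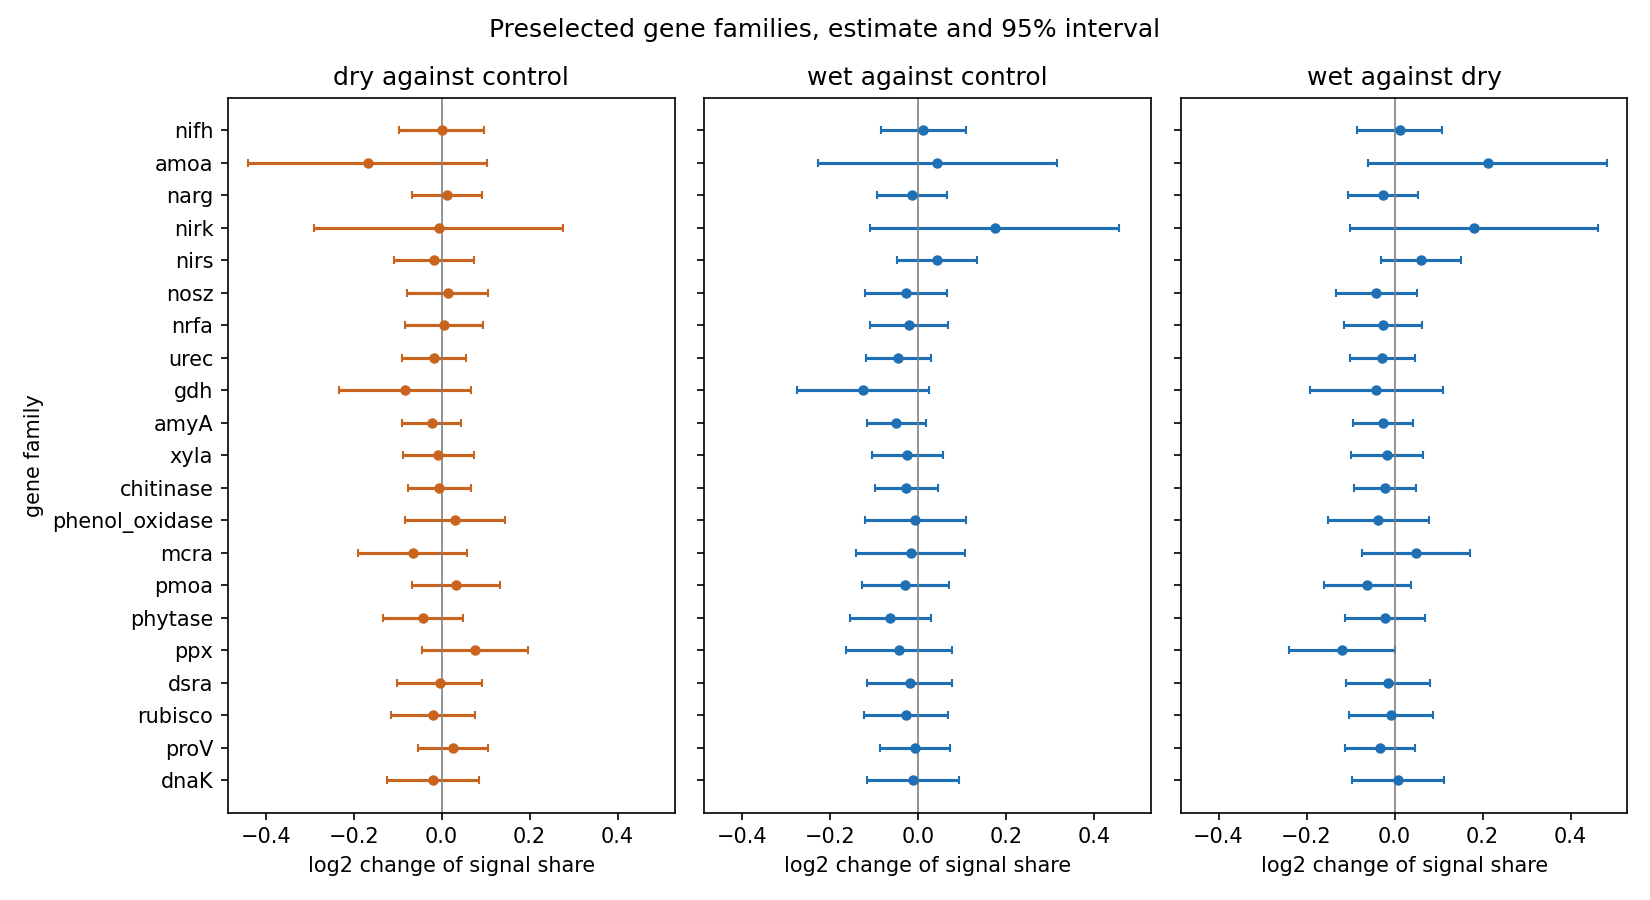
Log2 change of the share of array signal for the 21 gene families chosen beforehand, with 95% intervals (bars) from limma over 6 arrays per group, for dry against control, wet against control and wet against dry. Every interval includes 0, and the widest, for nirk, reaches 0.28 to either side of its estimate.

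The third comparison, wet against dry, set the ends of the precipitation range against each other. Limma called 0 of 669 families higher and 0 lower, with 24 at an unadjusted p under 0.05 (4 higher, 20 lower) and a smallest adjusted p of 0.833. The highest of the 21 chosen families was amoa, at 118 ± 19.2 against 102 ± 15.5 ppm in wet against dry arrays (log2 change 0.21, 95% interval -0.060 to 0.48), and the lowest ppx, at 8220 ± 282 against 8978 ± 1107 ppm (log2 change -0.12, 95% interval -0.24 to 0.00068). Without dry replicate 3, ppx was at -0.054, and without isolated bright values at -0.017. The nitrite reductase nirk, at 0.18, was at 0.011 without wet replicate 4. The denitrification genes narg (-0.027, -0.11 to 0.053), nirs (0.061, -0.030 to 0.15) and nosz (-0.041, -0.13 to 0.051), nifh (0.012, -0.085 to 0.11), amyA (-0.026, -0.094 to 0.041), chitinase (-0.022, -0.093 to 0.050) and pmoa (-0.062, -0.16 to 0.037) had intervals that included 0, as did the rest of the 21. In total 6 lay above 0 and 15 below, none passing when adjusted over the list alone (limma, smallest adjusted p = 0.796).

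By smallest p, the phage gene lysin (log2 change 0.72, 95% interval 0.28 to 1.16; 6 of 6 wet arrays above the dry mean), the plant virus gene replicase_Tombusvirus (0.27, 0.047 to 0.50; 6 of 6) and the proline transporter opuE (0.12, 0.0098 to 0.23; 5 of 6) stood higher in wet arrays. P450 (-0.19, -0.29 to -0.084), replicase_Carmovirus (-0.24, -0.41 to -0.076) and asp_5f0_stress (-0.27, -0.47 to -0.077) stood lower, each on 6 of 6 wet arrays. The limma adjusted p of all 6 was 0.833. The osmotic stress list, of which opuE is a member, had 1 family above 0 and 4 below, and held 2.24% ± 0.118 against 2.29% ± 0.0975. Adjusted over the list alone, 1 family of the electron transfer category passed, against 0 over all families. This was P450, already named above for its small p, so the pass is no further evidence. Phosphorus genes held 1.27% ± 0.0359 against 1.36% ± 0.101 in wet against dry arrays (exact permutation p = 0.0108, adjusted p = 0.444, and unadjusted exact p = 0.357 without isolated bright values). Camera called 0 of 41 lists (0 at an unadjusted p under 0.05, smallest adjusted p = 0.993, and 0.799 with an estimated correlation), and the exact test of shares called 0, with 2 at an unadjusted p under 0.05. The list medians lay between 0.011 and 0.089, beside 0.039 over all probes, while 16 of the 25 shares were lower in wet arrays. Of all families 70.9% lay below 0, and 58.3% without isolated bright values. In that setting limma gave 25 families at an unadjusted p under 0.05 (11 higher, 14 lower).

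Limma called 0 probes higher and 2 lower of 56459 in wet against dry arrays, with 2615 (4.63%) at an unadjusted p under 0.05. These were again nagg (log2 change -4.18 ± 0.18 SE, adjusted p = 2.3e-07) and Mex (-1.68 ± 0.18 SE, adjusted p = 0.0179), each on the same lone dry value. The count was 1 without control replicate 2, dry replicate 1 or 4, or wet replicate 3 or 4, and 6 without dry replicate 2. Numbers of listed probes (exact adjusted p = 0.541) and Shannon indices (exact adjusted p = 0.468) did not differ between wet and dry arrays.

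The gene composition of the arrays as a whole did not separate by group. In a permutation test on Bray-Curtis distances the 3 groups accounted for 10.1% of the variation, where 11.8% is the value chance gives (permutation p = 0.773). Dry and control arrays gave 7.31% (exact p = 0.810), wet and control 7.25% (exact p = 0.797) and wet and dry 8.72% (exact p = 0.457), with 9.09% by chance and an adjusted p of 0.810 for each. Pairs of arrays lay 0.109 ± 0.0120 apart within groups (45 pairs) and 0.107 ± 0.0133 between groups (108 pairs). Dry arrays lay farther from the centre of their group, at 0.0747 ± 0.00526, than control arrays at 0.0661 ± 0.00447, with 6 of 6 dry arrays above the control mean (exact permutation p = 0.00649, adjusted p = 0.0195, n = 6 each). For this test and those below, the centres were not recomputed in each arrangement, so the p-values are approximate. Over the probes listed on all arrays the distances were 0.0199 ± 0.00384 and 0.0196 ± 0.00446 and the difference did not pass (exact adjusted p = 0.931). It also failed to pass without control replicate 3 or 4 or without any of dry replicates 1 to 5, where the exact adjusted p lay between 0.0519 and 0.422. Wet arrays, at 0.0698 ± 0.00657, differed from neither control (exact adjusted p = 0.281) nor dry arrays (exact adjusted p = 0.260). The wet against dry difference of -0.00497 was -0.00872 without wet replicate 5, and then passed (exact adjusted p = 0.0162).

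**Figure D4:**
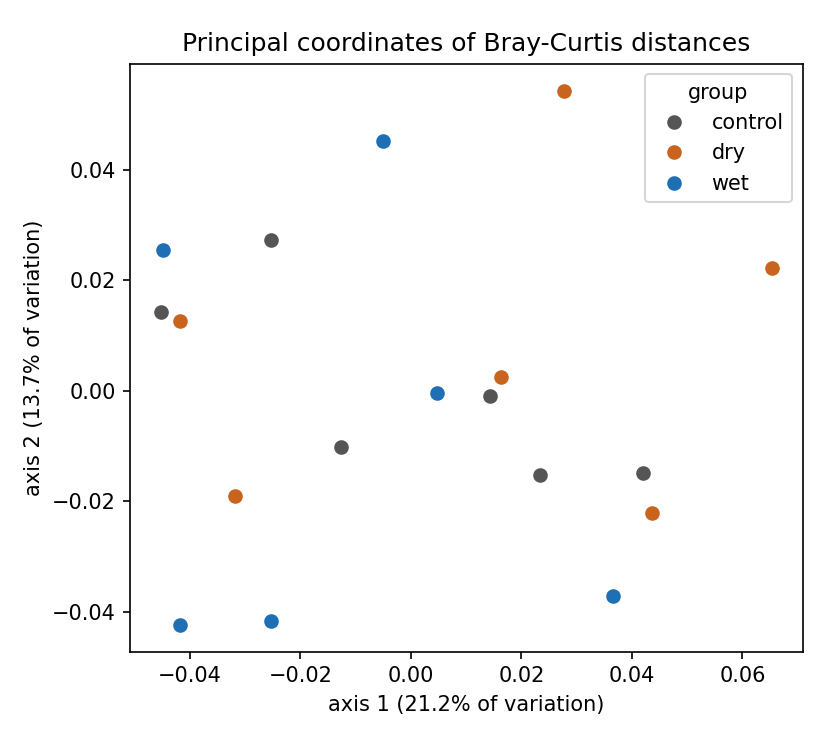
Principal coordinates of Bray-Curtis distances between the 18 arrays (axis 1, 21.2% of the variation; axis 2, 13.7%; no units), with 1 point per array coloured by precipitation group. Arrays of the 3 groups are interspersed.

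The intervals show, for 1 family at a time, which differences in signal share the spread between arrays of a treatment leaves possible. They were not adjusted over the 669 families. If each treatment stands for 1 plot, they leave out the spread between plots and do not bound an effect of precipitation itself. The median 95% interval reached 0.14 log2 units to either side of its estimate, and for 90.3% of families in dry against control, 89.8% in wet against control and 89.4% in wet against dry it lay within 0.5 of 0. In a simulation of dry against control on the 669 families, limma recovered 33% of changes of 0.15 log2 units, 65% of changes of 0.3 and 89% of changes of 0.6. With 57403 probes it recovered 52% of changes of 0.5 log2 units and 96.4% of changes of 1. Within each level, changes of all sizes were put in together, up and down in equal number. Over 5 sets there were 100 families and 250 probes of each size. A change in a single family would face a stricter adjusted threshold, and removing the group means narrows the spread. Recovery in the real arrays may therefore be lower.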

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

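Tests on nagg and Mex, on the isolated bright values and on the spread of the dry arrays were chosen after those results had been seen, and the splits of the samples were planned. In each of 210 groups of 6 values (70 measures in 3 groups), the array farthest from the others was compared with the range of its group. Of these, 24 had an array standing apart by more than the 95% critical gap. For independent, normally distributed values chance alone gives about 5%, or 10.5. The measures overlap and some families entered by their smallest p, so these counts do not show an excess over chance. The values are shares of the array signal.

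Among gene families, Hmd was at 67.4 ppm on dry replicate 3, next to 21.4 on the nearest array, ferric_reductase_transporter at 64.9 ppm on dry replicate 6, next to 40.2 on the nearest array, and glutamate_synthase_protist at 161 ppm on control replicate 6, next to 100.1 on the nearest array. The nitrite reductase nirk was at 5126 ppm on wet replicate 4, next to 2626 on the nearest array, and ppx at 11226 ppm on dry replicate 3, next to 8733 on the nearest array. On those arrays, probes listed on no other array stood at 437831 (nirk) and 481682 (ppx). Without isolated bright values, nirk in wet against control moved from a log2 change of 0.17 to 0.021. In dry against control, ppx moved from 0.076 to 0.0070, while ferric_reductase_transporter (0.36 to 0.37) did not shrink. Nor did sidC in wet against control (0.30 to 0.34). The sidC family stood low at 12.5 ppm on control replicate 5, next to 21.04 on the nearest array, and at 18.6 ppm on dry replicate 4, next to 24.6 on the nearest array. P450 was at 123 ppm on control replicate 5, next to 109.8 on the nearest array, and axe at 349 ppm on control replicate 6, next to 322 on the nearest array. Among carbon lists, hemicellulose degradation was at 1.65% on control replicate 6 (nearest array 1.33%), chitin degradation at 1.58% on dry replicate 3 (nearest array 1.38%) and methane at 0.338% on dry replicate 2 (nearest array 0.311%). The phosphorus list was at 1.56% on dry replicate 3 (nearest array 1.35%). Sulfur was low at 2.20% on control replicate 6 (nearest array 2.24%) and at 2.13% on dry replicate 3 (nearest array 2.22%). Among stress lists, heat shock and protein stress was at 0.867% on dry replicate 3 (nearest array 0.916%), oxygen limitation at 2.64% on dry replicate 3 (nearest array 2.44%), nitrogen limitation at 1.00% on wet replicate 2 (nearest array 0.609%) and glucose limitation at 0.0670% on dry replicate 5 (nearest array 0.0604%). Phosphate limitation was at 1.21% on control replicate 6 (nearest array 1.25%) and sigma factors at 2.35% on wet replicate 6 (nearest array 2.52%). By organism, fungal probes held 3.27% on control replicate 3 (nearest array 2.88%), bacterial probes 85.3% on wet replicate 6 (nearest array 93.0%) and viral probes 8.69% on wet replicate 6 (nearest array 0.505%). Some flagged lists held a bright probe listed on that array alone. Mannanase (hemicellulose) stood at 437383 on control replicate 6 and glnA (nitrogen limitation) at 548243 on wet replicate 2. On dry replicate 3 these were acetylglucosaminidase (chitin) at 461366 and fnr (oxygen limitation) at 481652.

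The probes nagg and Mex passed the test in both comparisons with the dry group, on 1 dry value each. The nagg value is also 1 of the isolated bright values. A candidate explanation is that a lone value in a group leaves the spread to the other arrays and passes too easily. In 198 other splits of the arrays, 318 of 343 calls (92.7%) rested on probes with 1 listed array in a group, although such probes were 1.47% of those tested. An earlier test, a filter on listed arrays per group, removed both probes by construction and so decided nothing. Whether the dry soils held more of either gene stays open, as the other dry arrays listed no value.

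Of 100 splits of the 12 arrays of a comparison, the real one included, 61 gave at least the 2 probes of the real split in dry against control (highest other 10) and 29 at least 2 in wet against dry (highest other 7), so chance is not excluded for these counts. A real count of 0 is reached by every split, 100 of 100, which says nothing about chance. This applies to the probes in wet against control (highest other 5) and to the families in dry against control (highest other 4), wet against control (highest other 2) and wet against dry (highest other 6).

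Wet replicate 6 had the lowest Shannon index, 9.45, and 75.3% of families lay below 0 in wet against control. Isolated bright values are a candidate source of both. Without them the index of wet replicate 6 was 9.99, inside the range of the other arrays (9.80 to 10.07), and 49.5% of families lay below 0. The bright values on wet replicates 4 and 6 made up 7.36% and 8.59% of those arrays' signal, and on dry replicate 3 5.86%. For bright values in general, these tests do not separate a fault of spot, scan or scaling from a real excess of the target DNA. On wet replicate 6, the value of 10252300 on the RdRp_Picornavirales probe of Human rhinovirus 26 made up 8.24% of the signal. DNA was labelled, so this signal on an RNA virus probe is not a measure of viral genomes. That value therefore gives no evidence of an excess of the virus in the soil. What produced it was not tested, and no biological explanation was tested.

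Dry arrays lay farther from their group centre than control arrays (0.0747 against 0.0661). Isolated bright values do not account for it, since without them the difference kept its size, 0.0739 ± 0.00563 against 0.0658 ± 0.00455 (SD, n = 6), with an exact p of 0.0152. Over the probes listed on all arrays the distances were 0.0199 and 0.0196 (exact permutation p = 0.931). With Jaccard distances, which use only which probes each array listed, the difference was 0.0173 (exact permutation test, adjusted p = 0.0195). Both results go with a difference in which probes each array listed. Dry arrays also ranged most widely in the number of listed probes (SD 4192, against 1956 in control arrays), which may come from the detection filter of each array. An effect of less precipitation on how patchy the soil was stays open, and cannot be told apart from a property of the plot, as there appears to be 1 plot per treatment.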

How the results depend on the processing

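Settings without isolated bright values, with at least 3 listed arrays in each group, for list shares and for the distance to group centres were chosen after the data were seen. The count of changed families was 0 in every comparison and setting (smallest adjusted p = 0.0661, wet against dry without dry replicate 3). The count of called lists was 0 in the settings run on lists, which did not include leaving arrays out (smallest adjusted p = 0.444). None of 2688 recomputed values of named families passed, and 198 had the other sign, which concerns no call. Numbers of listed probes, Shannon indices and composition stayed on their side of the threshold under the settings run on each (smallest adjusted p = 0.240, 0.169 and 0.430).

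Counts of changed probes moved between 0 and 8. In dry against control (2 in the report) the count was 1 with arrays scaled to the same total, 1 with median centring, 1 with blanks at the lowest listed value, 1 with only the groups compared and 1 without isolated bright values. It was 0 with probes listed on all arrays, 0 with at least 3 listed arrays per group, 4 with no filter beyond 3 listed arrays and 4 (3 higher, 1 lower) with an intensity trend and robust variances. In wet against dry (2 in the report) the count was 1 under total scaling, 1 under median centring, 1 with only the groups compared, 1 without isolated bright values and 3 with an intensity trend and robust variances. It was 0 with probes listed on all arrays, 0 with blanks at the lowest value, 0 with at least 3 arrays per group, and 8 (2 higher, 6 lower) with no filter. In wet against control (0 in the report) it was 2 with no filter. Fewer probes with a lone value are tested where the count is 0 by a stricter filter; for the rest the cause was not tested.

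With arrays left out in turn, dry against control gave 0 to 6 probes: 0 without dry replicate 4, 1 without control replicate 3, dry replicate 1 or any of wet replicates 3 to 6, 4 without control replicate 1 and 6 without dry replicate 2. Wet against control gave 0 to 2: 2 without control replicate 1 or 2, and 1 without control replicate 4 or 6 or wet replicate 5. Wet against dry gave 1 to 6: 1 without control replicate 2, dry replicate 1 or 4, or wet replicate 3 or 4, and 6 without dry replicate 2.

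The groups share replicate numbers, and the labels do not say that a number marks a place or a day. Over 18 same-numbered pairs, residuals correlated at -0.182 to 0.482 (mean 0.162, against -0.0323 for other pairs, permutation p = 0.00106), 12 of 18 above 0.1, and 13 of 18 arrays correlated best with an array of their own number, a hint from the data, not the design. With the replicate block, limma called 3 probes (2 higher, 1 lower) in wet against control and 4 (2 higher, 2 lower) in wet against dry. In dry against control it called 3 (2 higher, 1 lower). The block left families, lists, listed probes, Shannon indices and composition on their side of the threshold, and was not run for the distance to group centre.

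The dry against control difference in distance to group centre, 0.0086, was 2.30e-04 over probes listed on all arrays (adjusted p = 0.931; range over its settings 0.0162 to 0.931), where fewer probes enter. Leaving arrays out gave 0.00473 to 0.0115, and the call ended without control replicate 3 or 4 (both adjusted p = 0.0519) and without dry replicates 1 to 5 (0.195, 0.0649, 0.0909, 0.422 and 0.214). For wet against dry the range was -0.00872 to -0.0011, and -0.00872 without wet replicate 5 passed (adjusted p = 0.0162). Signal over background is not known for these arrays, and median intensity was 2.14 to 3.14 times the lowest listed value.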

Other observations

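The lineages deposited with the probes gave the makeup of the signal by phylum, a test chosen after the other results were seen. Probes of Actinobacteria held 25.8% ± 0.746 of the signal (SD over 18 arrays), Alphaproteobacteria 21.3% ± 0.541, Gammaproteobacteria 14.4% ± 0.414 and Betaproteobacteria 11.6% ± 0.308. Firmicutes followed with 4.74% ± 0.271, Deltaproteobacteria with 3.20% ± 0.0817 and the fungal phylum Ascomycota with 2.29% ± 0.122. These shares depend on how many probes the array carries for each lineage, 12737 listed ones for Actinobacteria and 507 for Acidobacteria, and so do not give the abundance of the organisms.

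No lineage group passed the test between treatments. Actinobacteria, which include filamentous and drought-tolerant bacteria, held 26.0% ± 0.332 in control, 26.0% ± 0.555 in dry and 25.3% ± 1.04 in wet arrays (SD, n = 6). Acidobacteria held 0.484% ± 0.0151 in control, 0.487% ± 0.0175 in dry and 0.478% ± 0.0204 in wet arrays, and Ascomycota 2.31% ± 0.173 in control, 2.28% ± 0.104 in dry and 2.27% ± 0.0937 in wet arrays. Of the archaea, Euryarchaeota held 1.499% ± 0.0425 in control, 1.495% ± 0.0633 in dry and 1.48% ± 0.0673 in wet arrays, and Crenarchaeota 0.529% ± 0.0140 in control, 0.525% ± 0.0155 in dry and 0.529% ± 0.0282 in wet arrays. Nitrospirae, which include nitrite oxidisers, held 0.0597% ± 0.00374 in control, 0.0604% ± 0.00332 in dry and 0.0603% ± 0.00548 in wet arrays. Of 25 groups with at least 100 listed probes, the exact permutation test called 0 in each comparison, with 0 at an unadjusted p under 0.05 (smallest adjusted p 0.976 for dry against control, 0.984 for wet against control and 0.970 for wet against dry). Without isolated bright values these counts were 0 as well (smallest adjusted p 0.989, 0.937 and 0.994).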
